A study of Mus musculus with 3 samples.

How the data were processed

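Chromatin immunoprecipitation followed by sequencing was done on mouse embryonic stem (ES) cells with antibodies against TET2, OGT and H2B S112GlcNAc, with 1 library per antibody. No input or IgG library was among the samples, and none was used here. Per the labels' protocols, nuclei were sonicated, fragments bound by the antibody were joined to adaptors, selected by size on a gel and amplified by PCR. The 3 deposited files list aligned reads, 1 read per line, each 44 bp long, with start, end, read name, score and strand. The deposited score was the same constant in every line and carried no measurement. Per the submitters' processing notes, the build was mm9 and the tools named were CASAVA 1.4 and Bowtie 0.12.2, with no role or order given. How reads with several matches in the genome and repeated reads were handled is not given in the sources used here. The read names of all 3 files pointed to the same flow cell lane.

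The TET2 and H2B S112GlcNAc files name chromosomes directly and the OGT file uses sequence identifiers of the same assembly. Whether the files share 1 coordinate system was checked at the 1000 positions with the most reads in a library. TET2 and OGT shared 894 of them, TET2 and H2B S112GlcNAc 840, and OGT and H2B S112GlcNAc 815. The correlation of log2(reads + 1) at these positions was 0.97 for TET2 and OGT and fell to 0.73 when the positions were moved by 1 bp.

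Depth was 3832237 reads for TET2, 2179445 for OGT and 4647963 for H2B S112GlcNAc. Reads at the same position and strand were counted once, which left 3297665, 1878601 and 4024073 positions. Each 5′ end was moved 100 bp towards the fragment centre, and counts were made on chromosomes 1 to 19 and X. The usable genome was the 255759 stretches of 10 kb with a read in any library, which is 96.9% of the span of these chromosomes. Enriched regions were called in windows of 500 bp every 250 bp. The count in a window was set against the highest of the genome mean and the means of the surrounding 10 kb and 50 kb, with the window and 500 bp on each side left out of those means. A window passed with a Poisson tail under 0.01 after Benjamini-Hochberg adjustment over 10230353 windows and a count at least 4-fold over the background, and touching windows were merged. This is a rule within 1 library and no test between antibodies. Leaving the window out of its own background was chosen after seeing the data, because the ratio to a background that holds the window cannot exceed a fixed ceiling. Extreme bins were 1 kb bins in the top 0.1% of counts in each of the 3 libraries, and 1014 bins met this.

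Overlap was counted from 1 bp and set beside 100 circular shifts of the regions along each chromosome. The signal of a library at regions of another was its count in the central 750 bp over its count more than 2 kb and up to 5 kb from the centre, per bp, outside extreme bins. Correlations were Pearson's r of log2(RPM + 1), with RPM the count scaled to library size, and Spearman's rho over 1 kb bins, with a standard error from leaving out each chromosome in turn. Bins are not independent replicates. A correlation corrected for counting noise was the covariance of the counts divided by the root of the product of the variances, each less its mean. Regions that differ were found by a rule of size over the merged regions of the 3 libraries. The rule asked for at least 30 positions in the higher library, a ratio of counts scaled to library size of at least 4 and a 95% interval that lay above 2. Other scalings used the median count of 10 kb bins outside regions, or a trimmed mean of ratios that leaves out 30% of the ratios and 5% of the sums at each end. The interval of a median strand distance came from 10000 resamples of the regions. That of the ratio of the OGT fold to the H2B S112GlcNAc fold was a normal approximation on the log scale, for counting error alone. Other intervals are exact (Clopper-Pearson for shares and ratios, Poisson for densities) and cover counting error alone, since reads amplified by PCR are not independent molecules. With 1 library per antibody no difference has a replicate check, and no p-value between antibodies is given. A comparison therefore describes these libraries.

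The rules for calling, overlap, correlation and size were set before the data were examined, except that the window was left out of its background afterwards. Also set beforehand were the alternatives that keep every read, use a stricter Poisson tail of 1e-05, ask for 8-fold or draw each library down to the smallest. The same holds for those that leave out extreme bins, use no shift, use 5 kb bins or another scaling. Named regions follow a rule set at the same time. For each library they are the 8 with the highest fold, and for each pair the 4 with the highest ratio each way. Regions named from outside extreme bins, the signal at regions of another library, the noise-corrected correlation, the strand distances and the chromosome counts were chosen after seeing the data. Gene annotation of mm9 was not used here, and the gene table at hand belongs to another build (GRCm38.p6). Reads near start sites, occupied promoters and gene lists were therefore not analysed here, and the rule of size planned for promoters was applied to merged regions. Regions are given by coordinates in mm9, counted from 1, without gene names.

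The region rule was tested on simulated data drawn from the local means of each library. With no enriched region placed, it called 0 regions in each of the 3 simulated libraries. With regions placed, 3 of 158 calls at the depth of TET2 (1.90%), 0 of 91 at that of OGT and 0 of 211 at that of H2B S112GlcNAc lay outside them. The draws follow the Poisson background that the rule assumes, with no added spread. These values therefore give no rate of false calls for the real libraries. Of 200 regions placed at 10-fold, the rule found 17.5% at the depth of TET2, 7.00% at that of OGT and 27.0% at that of H2B S112GlcNAc. At 20-fold it found 58.0%, 38.0% and 77.5%. At 5-fold it found 2.00%, 0.500% and 1.00%. The rule of size passed 0 of 200 simulated regions with equal density in each of the 6 directions. With 40 positions expected in the higher library it passed at most 1.50% at a true ratio of 2, 16.5% to 54.5% at 4 and 70.5% to 94.0% at 8, so it misses many differences. The noise-corrected correlation returned 0.899 for TET2 and OGT where 0.9 had been simulated. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.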

Results

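TET2 is an enzyme that oxidises 5-methylcytosine in DNA, OGT is the transferase that attaches O-linked N-acetylglucosamine (GlcNAc) to proteins, and H2B S112GlcNAc is histone H2B carrying this sugar on a serine. The series mapped all 3 in mouse ES cells of C57BL/6 origin, grown without feeder cells, by chromatin immunoprecipitation and sequencing. The question the design poses is where the 3 lie relative to each other. Each antibody had 1 library. The TET2 library held 3832237 aligned reads, the OGT library 2179445 and the H2B S112GlcNAc library 4647963. Repeats of a position and strand made up 13.9%, 13.8% and 13.4% of the reads. Counted once, the positions gave a mean density of 1.29, 0.734 and 1.57 per kb.

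TET2 gave the most enriched regions, 9660, against 1817 for OGT and 2779 for H2B S112GlcNAc. The regions were narrow, with a median width of 750 bp for TET2 and OGT and 500 bp for H2B S112GlcNAc. The median fold over the local background was 10.9 for TET2, 16.3 for OGT and 10.2 for H2B S112GlcNAc. A shallower library needs a higher fold to pass the Poisson tail, and OGT had the fewest reads. These medians therefore do not rank the strength of enrichment between libraries. The regions held 4.33%, 1.91% and 1.37% of the positions of their library. When the libraries were drawn down to the depth of OGT, 4033 regions were called for TET2 and 697 for H2B S112GlcNAc, so the order of OGT and H2B S112GlcNAc depended on depth. Without extreme bins the counts were 8918, 880 and 2117. Leaving the window out of its background was chosen after seeing the data, and with it kept in the counts were 6253, 835 and 1520.

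The regions with the highest fold were largely the same places in all 3 libraries. The highest for TET2 lay on chromosome 18 at 90771251 to 90772500, with 645 TET2, 539 OGT and 667 H2B S112GlcNAc positions, and a fold of 863. On chromosome 9 at 35112251 to 35113500 the TET2 fold was 826 and the H2B S112GlcNAc fold 771, and the OGT region starting at 35112501 had a fold of 1410. On chromosome 12 at 3109501 to 3110500 the folds were 581 for TET2, 948 for OGT and 428 for H2B S112GlcNAc. On chromosome 2 at 181747001 to 181748250 they were 645, 788 and 623, on chromosome 6 at 103598501 to 103599750 they were 374, 567 and 308, and on chromosome X at 166526751 to 166528000 they were 444, 487 and 267. On chromosome 11 at 121843251 to 121844250 the TET2 fold was 341 and the H2B S112GlcNAc fold 262, and on chromosome 2 at 57481501 to 57482500 the OGT fold was 441 and the H2B S112GlcNAc fold 270. All of these shared places overlapped extreme bins. The region from 35112251 of chromosome 9 held 15824 TET2, 9119 OGT and 17636 H2B S112GlcNAc reads at 623, 545 and 676 positions. That of chromosome 12 held 19082, 11291 and 19819 reads at 377, 348 and 404 positions. Repeats were fewer at the rest. The chromosome 12 place lies within the 3 deepest stretches, where values given below argue against enrichment by an antibody. For the other shared places this stays open. The list for TET2 also held a region with few reads in the other libraries, on chromosome 18 at 7608501 to 7610000, with 648 TET2, 19 OGT and 33 H2B S112GlcNAc positions and a fold of 647. The list for OGT held a region on chromosome 17 at 4625751 to 4627000 with 348 OGT, 132 TET2 and 75 H2B S112GlcNAc positions and a fold of 809.

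Outside extreme bins the leading regions differed between libraries. This follows in part from the choice, since extreme bins are high in all 3 libraries by definition. For TET2 the highest fold, 202, was on chromosome 5 at 66857251 to 66858250, with 137 TET2, 8 OGT and 11 H2B S112GlcNAc positions. For OGT it was 136, on chromosome 1 at 45007751 to 45008500, with 50 OGT, 14 TET2 and 10 H2B S112GlcNAc positions. For H2B S112GlcNAc it was 39.4, on chromosome 15 at 6266501 to 6267500, with 33 H2B S112GlcNAc, 27 TET2 and 24 OGT positions.

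Most OGT regions and most H2B S112GlcNAc regions overlapped a TET2 region. The share was 62.5% for OGT (95% interval 60.2 to 64.7, 1135 of 1817) and 62.0% for H2B S112GlcNAc (60.2 to 63.8, 1723 of 2779). After circular shifts the mean share was 0.441% and 0.420%, and the highest of 100 shifts was 0.826% and 0.792%. The shifts stand for random placement alone. Regions that recur for a reason unrelated to the antibody would exceed them as well, and no input library was used here. Of the OGT regions, 42.1% (39.8 to 44.4) overlapped an H2B S112GlcNAc region, against 0.125% after shifts. In the other direction 11.7% of TET2 regions overlapped an OGT region and 17.8% an H2B S112GlcNAc region. Merging the regions of the 3 libraries gave 11337, of which 714 were called in all 3, 7517 in TET2 alone, 624 in OGT alone and 999 in H2B S112GlcNAc alone.

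Without extreme bins the OGT overlap was 56.4% with TET2 and 30.3% with H2B S112GlcNAc, the H2B S112GlcNAc overlap with TET2 was 54.8%, and 233 of 10220 merged regions were called in all 3. With the libraries also drawn down to 1 depth, the overlaps were 30.7%, 8.30% and 41.3%. Extreme bins were picked for high counts in all 3 libraries, so leaving them out lowers the sharing in part by construction. The reads of each library were also split at random into equal parts, of 1648795 and 1647162 positions for TET2, 939004 and 938577 for OGT and 2012024 and 2009947 for H2B S112GlcNAc. Regions called in a part of the TET2 library overlapped those of the other part in 29.6% of cases (27.8 to 31.4), and the value was 40.6% (34.4 to 46.9) for OGT and 21.9% (17.5 to 26.9) for H2B S112GlcNAc. The parts were called outside extreme bins and held fewer positions than the whole libraries. These shares therefore cannot be ranked against the overlaps between whole libraries.

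**Figure D1:**
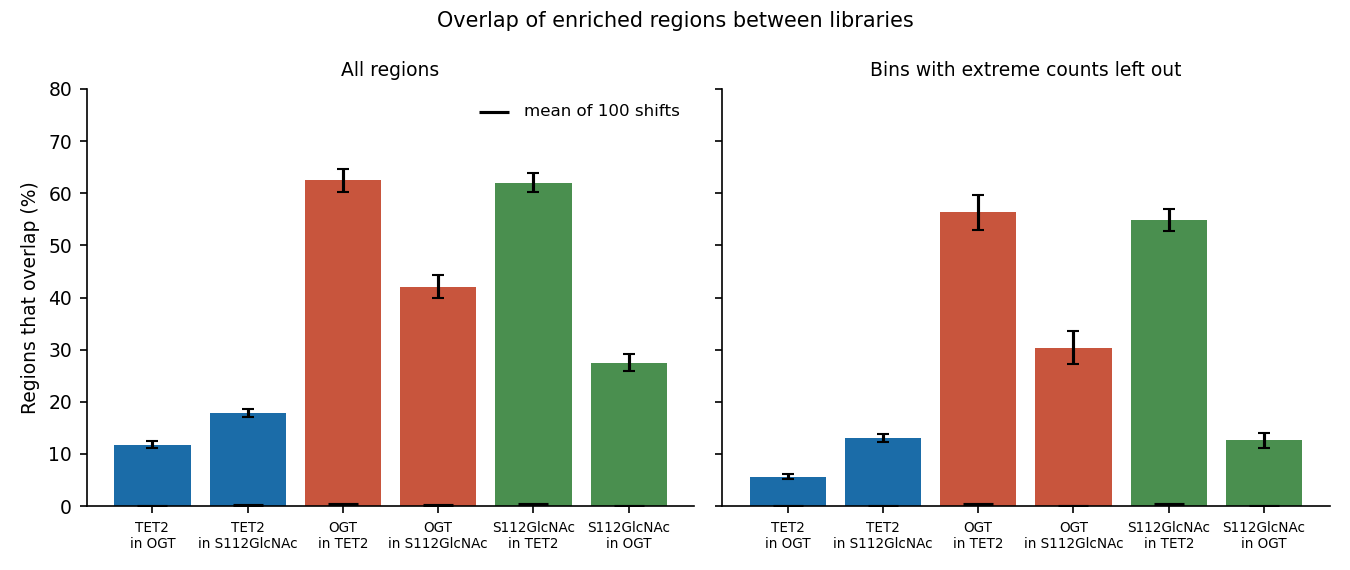
Bars give the percentage of the regions of one library that overlap a region of another by at least 1 bp, for all regions (left) and with extreme bins left out (right); error bars are exact 95% intervals for counting error and black dashes the mean of 100 circular shifts. The OGT and H2B S112GlcNAc overlaps with TET2 stand at 62.5% and 62.0% on the left, and all dashes lie below 1%.

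Measured without a call in the second library, reads of each antibody were concentrated at the regions of the others. At the 8844 TET2 regions outside extreme bins, OGT reads were 5.26-fold (5.19 to 5.34) and H2B S112GlcNAc reads 4.27-fold (4.23 to 4.32) denser in the centre than in the flanks. At least 3 OGT positions were found in 61.4% of these regions (60.4 to 62.4), against 5.18% of windows 3 kb away, and at least 3 H2B S112GlcNAc positions in 89.0% (88.3 to 89.6) against 19.9%. At the 862 OGT regions the fold was 8.79 (8.52 to 9.06) for TET2 and 5.95 (5.77 to 6.14) for H2B S112GlcNAc. At the 2077 H2B S112GlcNAc regions it was 8.83 (8.65 to 9.01) for TET2 and 7.35 (7.14 to 7.56) for OGT.

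A library's own fold, with regions called in a random part of its reads and measured in the rest, was 9.53 (9.30 to 9.77) for TET2, 12.6 (11.9 to 13.4) for OGT and 8.16 (7.61 to 8.75) for H2B S112GlcNAc. Which regions are called depends on depth, so these values do not rank the libraries either. OGT and H2B S112GlcNAc densities rose with TET2 enrichment. From the lowest to the highest quartile of TET2 fold, among TET2 regions with fewer than 1.3 reads per position, the OGT fold was 3.30, 4.55, 6.22 and 7.81, and the H2B S112GlcNAc fold 2.97, 3.92, 4.99 and 6.23. The 95% intervals of neighbouring quartiles did not meet. In all 9 combinations of regions and reads the bins above the midpoint between flank and summit spanned 500 bp. With bins of 250 bp and calling windows of 500 bp this is near the resolution, so it does not compare the widths of the 3 signals. No input library was used here, so these folds hold any enrichment that does not depend on the antibody.

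**Figure D2:**
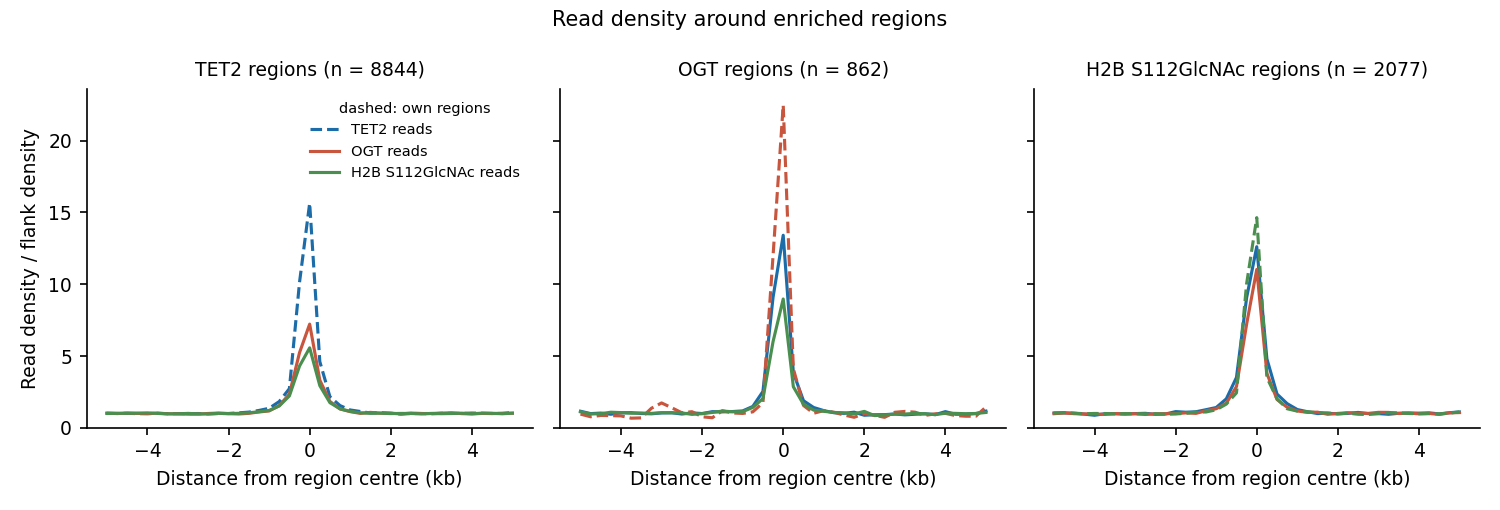
Mean read density in 250 bp bins from 5 kb upstream to 5 kb downstream of the centre of TET2, OGT and H2B S112GlcNAc regions outside extreme bins, divided by the density more than 2 kb away; dashed lines are the library in which the regions were called. At TET2 regions the central bin stands at 15.6 for TET2, 7.22 for OGT and 5.57 for H2B S112GlcNAc.

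Across the genome the counts of each pair of libraries were positively correlated, and the order of the pairs depended on depth. Most positions lay outside enriched regions, which held 4.33% of them for TET2, 1.91% for OGT and 1.37% for H2B S112GlcNAc. No input library was used here, so the correlations here and below hold any shared read density that does not depend on the antibody. Over 2557590 bins of 1 kb, Pearson's r was 0.435 (SE 0.0123 over chromosomes) for TET2 and H2B S112GlcNAc, 0.356 (SE 0.0106) for TET2 and OGT, and 0.348 (SE 0.0114) for OGT and H2B S112GlcNAc. Spearman's rho was 0.345 (SE 0.0113), 0.274 (SE 0.00953) and 0.279 (SE 0.00999). Most 1 kb bins hold few reads, and in bins with at least 5 reads over the 3 libraries rho was -0.0503 for TET2 and H2B S112GlcNAc, 0.00382 for TET2 and OGT, and -0.0491 for OGT and H2B S112GlcNAc. Choosing bins by the sum of the counts lowers rho by itself, and with the bins of each library in random order the same choice gave -0.508, -0.246 and -0.287. In 5 kb bins r was 0.680, 0.590 and 0.594. Drawn down to the smallest library, r in 1 kb bins was 0.289 (SE 0.0102), 0.302 (SE 0.00984) and 0.273 (SE 0.0101), so TET2 and H2B S112GlcNAc no longer led.

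With the counting noise removed and extreme bins left out, r over 1 kb bins was 0.929 (SE 0.00409) for TET2 and H2B S112GlcNAc, 0.753 (SE 0.0689) for TET2 and OGT, and 0.783 (SE 0.0703) for OGT and H2B S112GlcNAc. With the regions that met the rule of size in any direction left out, the 3 values were 0.943 (SE 0.00184), 0.931 (SE 0.00771) and 0.954 (SE 0.00814). These regions were picked because the libraries differed there, so a rise follows in part from the choice.

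**Figure D3:**
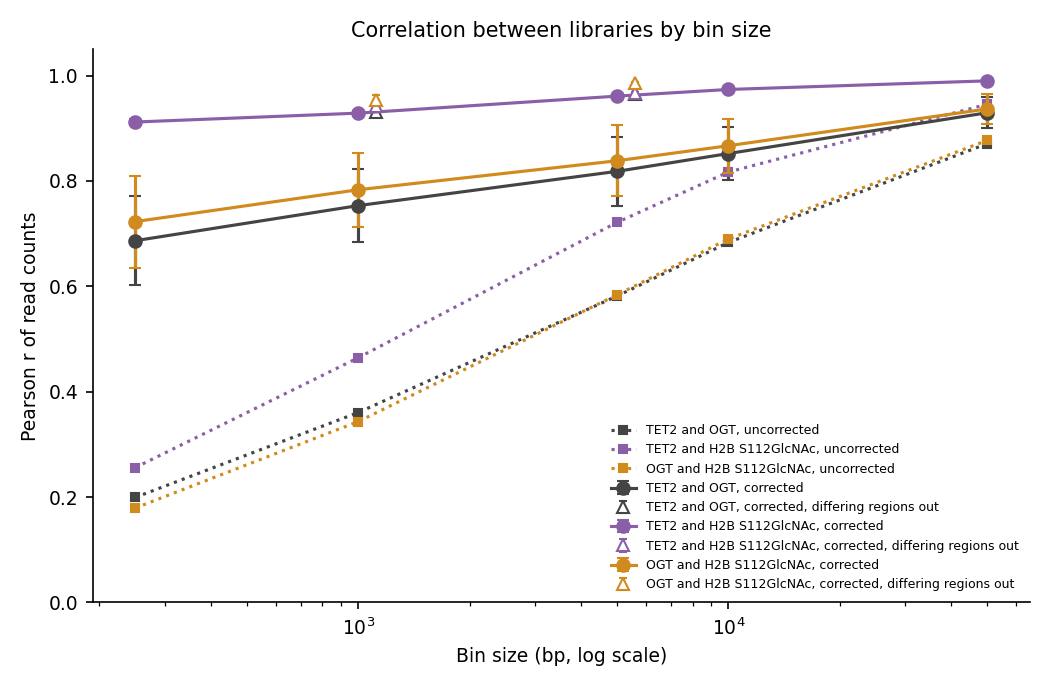
Pearson's r of read counts against bin size on a log axis, outside extreme bins, before (squares) and after (circles) removal of counting noise; triangles leave out the regions that met the rule of size, and error bars are standard errors over chromosomes. The corrected r at 1 kb rises for TET2 and OGT from 0.753 to 0.931 when these regions, picked for their difference, are left out.

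The rule of size between libraries asks for at least 30 positions, which 536 of the 11337 merged regions held in any library, so it says nothing about the rest. Of the regions that met it, those higher in OGT stood furthest apart. TET2 was higher than OGT in 37 regions and lower in 49, higher than H2B S112GlcNAc in 63 and lower in 1. OGT was higher than H2B S112GlcNAc in 64 and lower in 0. The median ratio of read density, scaled to the total of each library, was 45.6 in regions higher in OGT than in TET2, and 8.43 in regions higher in TET2 than in OGT. The floor of 30 positions asks for a higher density in the shallower OGT library, so part of this gap follows from the rule. Scaling by the trimmed mean of ratios changed the split to 10 against 66 for TET2 and OGT and to 12 against 4 for TET2 and H2B S112GlcNAc. Keeping every read gave 46 against 100 for TET2 and OGT. In 29 regions TET2 was higher than both others, in 49 OGT was, and in 0 H2B S112GlcNAc was.

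The largest ratios of TET2 over OGT were 78.6 (13.9 to 3127) on chromosome 18 at 67450751 to 67451750, with 138 against 1 positions, 35.9 (6.21 to 1440) on chromosome 2 at 173562501 to 173563500, with 63 against 1, 20.5 (3.45 to 832) on chromosome 5 at 129525501 to 129526750, with 36 against 1, and 19.4 (12.3 to 32.5) on chromosome 18 at 7608501 to 7610000. Over H2B S112GlcNAc the largest TET2 ratios were 33.6 (8.86 to 284) on chromosome 18 at 34671251 to 34672000, 26.8 (10.1 to 101) on chromosome 14 at 118574251 to 118575000, and 24.1 (11.4 to 61.0) and 24.0 (16.9 to 35.1) at the same 2 regions of chromosome 18 that led against OGT, starting at 67450751 and 7608501. The single region higher in H2B S112GlcNAc than in TET2 was on chromosome 7 at 19895251 to 19896250, with 34 against 4 positions, a ratio of 6.97 (2.48 to 27.0).

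The largest ratios of OGT over TET2 were 265 (46.9 to 10538) on chromosome 11 at 87889501 to 87890000, 236 (64.7 to 1960) on the same chromosome at 87894501 to 87895500, 123 (33.4 to 1025) on chromosome 7 at 106396251 to 106398000 and 121 (21.0 to 4853) on chromosome 7 at 134733751 to 134734500. Over H2B S112GlcNAc they were 323 (57.2 to 12859) on chromosome 11 at 87889501 to 87890000, 116 (60.8 to 256) at 87886251 to 87887500 of that chromosome, 111 (19.1 to 4483) on chromosome 3 at 133134001 to 133134750 and 107 (18.4 to 4314) at 133139001 to 133140000 of chromosome 3.

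The 49 regions higher in OGT than in both others fell into 30 loci, and 27 of the regions lay in 8 loci with more than 1 region. They held 0.497% of the OGT reads. At the locus with the most reads, on chromosome 7 from 134732751 to 134746500, the 4 regions held 3818 OGT, 16 TET2 and 25 H2B S112GlcNAc reads. The OGT reads there lay at 584 distinct positions. There 28 of 55 bins of 250 bp had no OGT position while 18 had at least 10. On chromosome 11 from 87886251 to 87895500 the 3 regions held 1667 OGT reads, and 18 of 37 bins had none. At the OGT mean of 0.734 positions per kb an empty bin of 250 bp is usual, so the filled blocks set these loci apart, not the gaps.

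**Figure D4:**
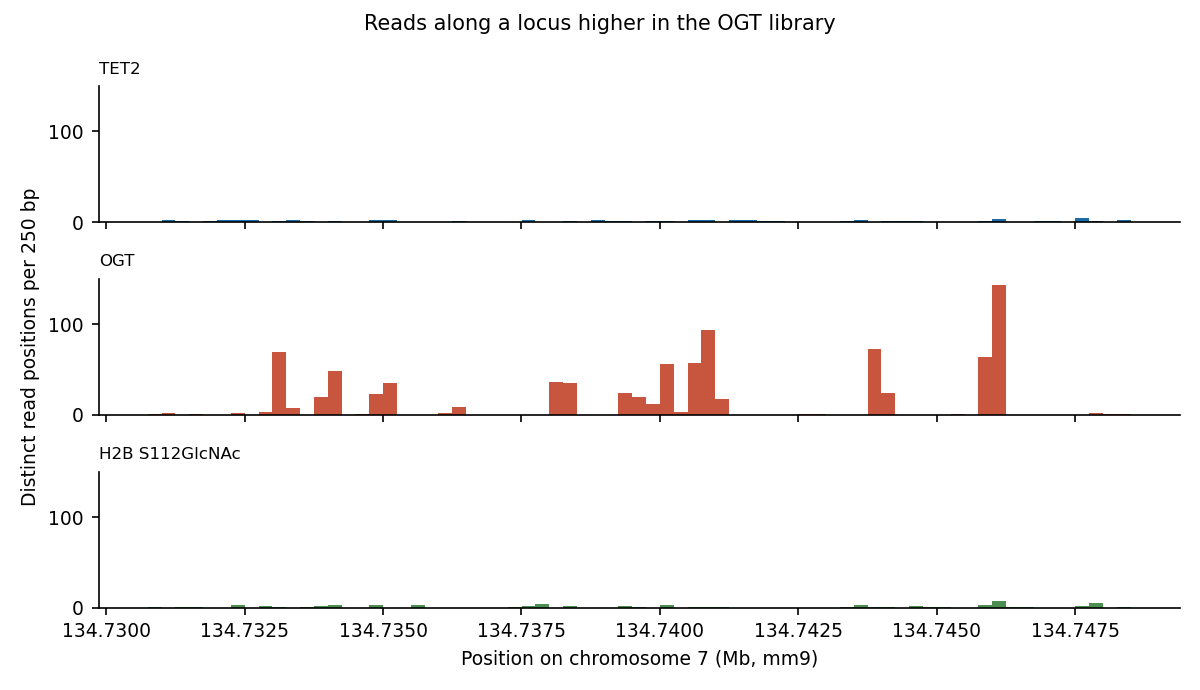
Distinct read positions per 250 bp of the TET2, OGT and H2B S112GlcNAc libraries along chromosome 7 (mm9), on 1 shared scale, at the locus with the most OGT reads among those with more than 1 region. OGT positions form separate blocks, of up to 143 per bin, with empty bins between them, and the other 2 libraries stay at or below 7.

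The strands of the reads also differed between these sets. In the 25 regions higher in TET2 than in both others with at least 15 positions on each strand, the median of the minus-strand 5′ ends lay 110 bp (95% interval over regions 94 to 124) to the right of the median of the plus-strand 5′ ends. In the 43 such regions of OGT the distance was 42.5 bp (39 to 44), and in 31 of them it was within 15 bp of the read length minus 1. The interval treats regions as independent, although 27 of the 49 regions higher in OGT lay in 8 loci. A distance of at least 70 bp was found in 24 of the 25 TET2 regions and in 3 of the 43 OGT regions. Of the 43 OGT regions 38 lay outside extreme bins, and 28 of the 38 had a distance near the read length. Among regions outside extreme bins that met no rule of size, 3 of 60 for TET2 and 2 of 10 for H2B S112GlcNAc had it, and for OGT only 1 region could be measured. In regions with extreme bins that met no rule of size, the median was 42.0 bp for TET2, 41.5 bp for OGT and 42.0 bp for H2B S112GlcNAc.

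**Figure D5:**
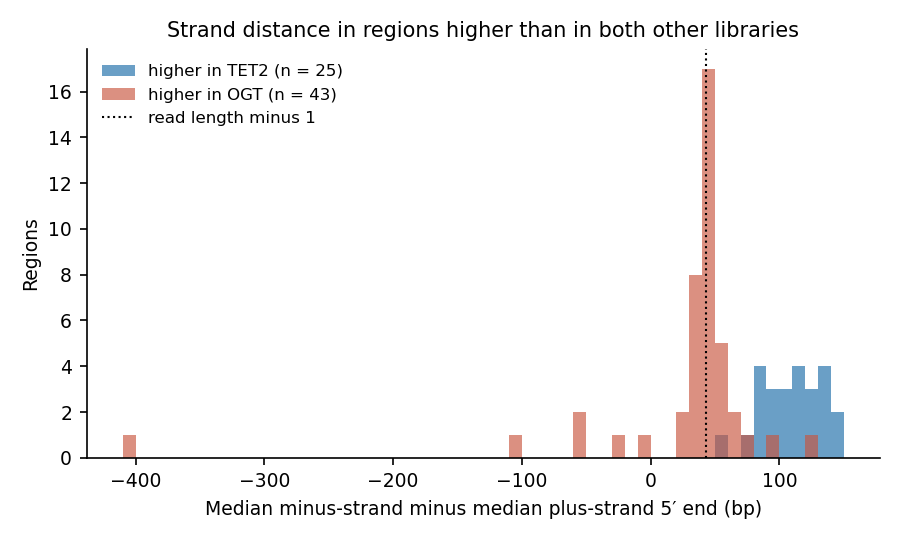
Number of regions by the distance in bp from the median plus-strand to the median minus-strand 5′ end, for the 25 regions higher in TET2 and the 43 higher in OGT than in both other libraries; the dotted line is the read length minus 1. The OGT regions centre on 42.5 bp and the TET2 regions on 110 bp.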

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

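Reads on chromosome Y and on the mitochondrial genome entered no comparison and were above the limit that a count of 0 allows. On chromosome Y there were 1187 TET2, 706 OGT and 1271 H2B S112GlcNAc reads, which is 0.0310%, 0.0324% and 0.0273% of each library. On the mitochondrial genome there were 894, 498 and 1209 reads, which is 0.0233%, 0.0228% and 0.0260%.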

How the results depend on the processing

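No paired analysis was possible because each antibody had 1 library. The alternatives for start sites, promoters and gene lists, including the narrower promoter window, autosomes alone and an estimated shift, were not run, since gene annotation of the build was not used here. The settings that keep the window in its background, join drawing down with leaving out extreme bins or leave out regions of 1.3 or more reads per position, and all settings for the fold at regions of another library, were chosen after seeing the data. Of 129 values of main results under an alternative, 57 stayed within 1.5 times (counts) or the 95% interval (other values), 70 moved and 2 changed sign. For the ratios at named regions 46 of 51 stayed and 5 moved. Fewer reads or stricter rules lower counts by construction. Leaving out extreme bins, which are high in all 3 libraries, lowers overlaps in part by construction. For the other changes, except that of rho in bins with at least 5 reads, the cause was not tested.

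Region counts for TET2, OGT and H2B S112GlcNAc were 3168, 633 and 812 with the Poisson tail of 1e-05, and 6253, 835 and 1520 with the window kept in its background. They were 4033 for TET2 and 697 for H2B S112GlcNAc when drawn down, 880 for OGT without extreme bins, and 3430, 880 and 276 with both. The overlaps of OGT with TET2, H2B S112GlcNAc with TET2 and OGT with H2B S112GlcNAc were 74.9%, 74.4% and 65.4% with the stricter tail, 43.5%, 66.9% and 23.4% drawn down, 56.4%, 54.8% and 30.3% without extreme bins, and 30.7%, 41.3% and 8.30% with both. At full depth, without extreme bins and without regions of 1.3 or more reads per position, they were 57.1%, 53.8% and 28.3%. With the window kept in its background the OGT overlaps were 72.5% with TET2 and 59.2% with H2B S112GlcNAc. Keeping every read gave 55.7% for H2B S112GlcNAc with TET2, and asking for 8-fold gave 39.3% for OGT with H2B S112GlcNAc. OGT regions overlapping both others numbered 707, and 399 with the stricter tail, 392 drawn down and 230 without extreme bins. Circular shifts were run for all regions, without extreme bins and with regions of 1.3 or more reads per position also left out, and the highest mean share was 0.441%.

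For TET2 and OGT, TET2 and H2B S112GlcNAc, and OGT and H2B S112GlcNAc, Pearson's r was 0.590, 0.680 and 0.594 in 5 kb bins, 0.131, 0.134 and 0.0726 in bins with at least 5 reads, and 0.302, 0.289 and 0.273 drawn down. Spearman's rho was 0.556, 0.646 and 0.566, then 0.00382, -0.0503 and -0.0491, then 0.232, 0.226 and 0.218. In bins with at least 5 reads the choice by the sum of the counts gave -0.246, -0.508 and -0.287 for bins in random order.

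With at least 10 reads asked for, TET2 was higher than OGT in 81 regions and than H2B S112GlcNAc in 251, OGT was higher than TET2 in 92 and than H2B S112GlcNAc in 137, and H2B S112GlcNAc was higher than TET2 in 9 and than OGT in 1. Scaling by the trimmed mean of ratios gave 10 for TET2 over OGT, 12 for TET2 over H2B S112GlcNAc and 4 for H2B S112GlcNAc over TET2. Keeping every read gave 100 for OGT over TET2 and 100 for OGT over H2B S112GlcNAc.

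Keeping every read, the folds at TET2 regions were 5.62 for OGT and 4.36 for H2B S112GlcNAc, at OGT regions 10.4 for TET2 and 6.95 for H2B S112GlcNAc, and at H2B S112GlcNAc regions 9.53 for TET2 and 8.41 for OGT. Without regions of 1.3 or more reads per position the fold was 5.03 for OGT at TET2 regions, and 8.59 for TET2 and 6.74 for OGT at H2B S112GlcNAc regions.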

Other observations

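The density of enriched regions differed between chromosomes, and X had the lowest in all 3 libraries. Outside extreme bins TET2 had 1.43 regions per Mb on X (1.25 to 1.63), 2.89 on chromosome 1, the lowest autosome, and 4.90 (4.51 to 5.31) on chromosome 11, the highest. H2B S112GlcNAc had 0.443 per Mb on X (0.347 to 0.558) and at most 1.03 (0.854 to 1.23), on chromosome 12. OGT had 0.154 per Mb on X (0.0996 to 0.227) and at most 0.538 (0.415 to 0.686), on chromosome 9. The median read density per 100 kb on X was 0.514 of the autosomal level for TET2, 0.531 for OGT and 0.533 for H2B S112GlcNAc, so fewer reads stood behind each window there.

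All tests in the next paragraphs were chosen after the results they concern had been seen, except the comparison with an input or IgG library, which was planned.

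OGT and H2B S112GlcNAc reads were enriched at TET2 regions, and all 3 libraries came from 1 lane, so TET2 reads assigned to the wrong library could give this. The TET2 region on chromosome 18 from 7608501, with 1488 TET2, 19 OGT and 34 H2B S112GlcNAc reads, allows at most 1.99 OGT and 3.19 H2B S112GlcNAc reads per 100 TET2 reads, while over 8674 TET2 regions with fewer than 1.3 reads per position the excess was 25.4 and 43.8 per 100 excess TET2 reads, more than wrong assignment allows. Repeats collapsed in the assembly would give equal folds, and the OGT fold was 1.19 times that of H2B S112GlcNAc (1.17 to 1.21), but the 3 stretches with the most reads span ratios of 0.858 to 1.21, so this does not decide. At TET2 regions, pairs of plus- and minus-strand 5′ ends about a read length apart were 2.72 times as frequent as far pairs for OGT, 2.32 times for H2B S112GlcNAc and 1.85 times for TET2. Pairs about 100 bp apart were 1.55, 1.56 and 1.83 times as frequent there, so TET2 reads at TET2 regions hardly favoured the read length. At OGT regions the values for pairs about a read length apart were 6.11, 4.31 and 2.98. The feature was thus strongest at OGT regions, where all 3 libraries had it, and no explanation for it was tested. Chromatin recovered more readily with any antibody also remains open, because there were 0 input or IgG libraries, and it cannot be told apart from a joint presence of the 3 on the same chromatin.

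The regions higher in OGT than in both others form another pattern. Sheared chromatin around a binding site would be expected to set the strands apart as in the TET2 regions, with a median of 110 bp (94 to 124). The OGT median of 42.5 bp (39 to 44) argues against sheared chromatin for these regions as a set, with regions of 1 locus counted as independent. This yardstick comes from the TET2 library. At TET2 regions OGT reads also favoured pairs about a read length apart (2.72 times as frequent as far pairs), and so did H2B S112GlcNAc reads (2.32). At OGT regions all 3 libraries had the feature (6.11 for OGT, 4.31 for H2B S112GlcNAc and 2.98 for TET2). It was thus strongest for OGT reads at OGT regions, but confined neither to the OGT library nor to the regions higher in OGT. The short distance by itself therefore does not set these regions apart from other signal. The blocks do not end where reads can no longer be placed, since in bins without an OGT position within 1 kb the other 2 libraries had 1.01 times their genome mean (0.829 to 1.21) around regions in loci with more than 1 region and 1.43 times (1.22 to 1.67) around the rest. DNA pieces with fixed ends, such as cloned or amplified sequence, would place both strands over the same interval, and 31 of 43 regions had the distance this gives, but among regions that met no rule of size a distance near the read length was also usual with extreme bins in all 3 libraries (medians 42.0, 41.5 and 42.0 bp), and outside them it was found in 3 of 60 TET2, 2 of 10 H2B S112GlcNAc and the 1 OGT region measured. It may contribute to the OGT library as a hypothesis, and whether the blocks match exons was not tested, since gene annotation of the build was not used here.

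Of the stretches with very many reads in all 3 libraries the 3 deepest, on chromosome 2 from 98502001 to 98508000, chromosome 9 from 2999001 to 3039000 and chromosome 12 from 3109001 to 3111000, held 8.12% of TET2, 8.01% of OGT and 8.30% of H2B S112GlcNAc reads. Enrichment by an antibody would be expected to differ between the libraries, and in these 3 the largest ratio between a pair of libraries was 1.21, which argues against it there. Of the other 608 stretches 88 differed at least 2-fold with a 95% interval above 1, up to 57.2-fold. Another 330 differed less than 1.5-fold, and the median of the largest ratio over the 608 was 1.47. For these other stretches it stays open. Sequence present in many copies but few in the assembly may account for the 3 deepest, and was not tested because no genome sequence was used here. No biological explanation was tested.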
